A study of Mus musculus with 8 samples.

How the data were processed

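The deposited tables hold raw read counts per gene symbol for 8 mouse hearts, with 1 table per mouse. Per the submitters' processing notes, reads were trimmed with Trimmomatic and aligned with STAR to the mouse genome mm10. The versions, settings and gene annotation are not given in the sources used here. Per the labels' protocols, RNA was isolated with Trizol from snap-frozen heart and libraries of polyadenylated RNA were prepared with the sequencing provider's standard protocol. Each table gives counts irrespective of strand and counts for each strand. Counts irrespective of strand were used, as fixed before the data were examined. The strand columns show that the libraries kept strand, since 2.66 to 5.31% of stranded gene reads lay opposite to the annotated strand. Counts of overlapping genes on opposite strands can therefore be mixed, which was examined with the stranded counts as an alternative. Reads that map to several places are not counted, so paralogous genes with near-identical sequence are undercounted.

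Of all reads, 33.0 to 38.9% were not assigned to a gene, made up mainly of reads in no annotated feature (18.6 to 22.3%) and of reads mapping to several places (11.8 to 14.1%). These lines were left out of library sizes and tests. The tables list 24411 gene symbols, of which 24020 were matched to GENCODE M21 (GRCm38, the same build as mm10), in part through synonyms in the RefSeq gene table, for positions, strands and biotypes. No symbol was of a mitochondrially encoded gene. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 14.6 to 97.4), so each counted as 1 replicate.

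Groups were taken from the labels (4 MerCreMer control and 4 YY1 KO mice, all 1 week after surgery). Genes were kept with edgeR's filterByExpr (minimum count 10, equal to 0.648 CPM, in at least 4 libraries), leaving 13506 genes with 99.9% of gene reads. Differences between genotypes were tested with edgeR 4.0.16 (TMM scaling, robust quasi-likelihood fit and F test, group as the single term) with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are YY1 KO minus control with their standard errors, and levels are CPM from TMM-scaled library sizes. CPM values of Xist and the Y-linked genes were computed from gene reads without scaling. Principal components used log2 CPM with a prior count of 2 and the 2000 most variable tested genes.

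Gene lists (22 functional and 15 of cell type or state markers) were fixed before the data were examined and tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each kind. They were also tested with an estimated correlation and with fry. With the preset correlation 13 of 21 functional lists with measured members and 3 of 15 marker lists passed. With an estimated correlation 0 passed (lowest adjusted p = 0.459 for functional and 0.830 for marker lists), and in fry 7 functional and 2 marker lists passed. Named genes followed a rule fixed in advance. It took Yy1, the 12 higher and 12 lower genes with the largest fold change among those with an adjusted p under 0.05, a mean CPM of at least 1, groups that did not overlap and a protein-coding biotype, leaving out predicted-gene and clone names, and up to 4 members with the smallest p of each list. Of the genes this rule took, 2 are not reported here. The sex-linked genes, and Nppa, Nppb, Acta1, Myh7 and Postn as genes that respond to load, were chosen after their values were seen.

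The test was checked on simulated counts drawn for the real genes with seeded changes in this design of 4 against 4 libraries. Over 13383 genes, 53.6% of genes changed 2-fold and 15.2% of genes changed 1.5-fold were recovered, and 4.3% of the calls were false. A missing call for a small change is therefore weak evidence of no change. The simulation gave 70 calls in all, against 5248 in the data, so its adjustment was stricter and recovery in the data may be higher. In a second simulated set, camera passed the changed list and also 1 of 20 unchanged lists, but simulated genes vary independently, unlike real ones.

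The alternatives were other scaling methods (RLE, upper quartile, library size alone), DESeq2 1.42.0, limma-voom, 2 other filters, stranded counts, the replicate number as a block, 1 surrogate variable (sva 3.50.0), and leaving out each library in turn. A term for sex and fits within the Xist-positive or Y-positive hearts were added after the data were seen. Genotype labels were also regrouped in the 35 possible splits of 4 against 4. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.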

Results

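Hearts from 8 C57BL/6 mice were profiled by sequencing of polyadenylated RNA 1 week after transverse aortic constriction, an operation that narrows the aorta and so raises the pressure against which the left ventricle pumps. In 4 mice the transcription factor Yin-Yang 1 (YY1, gene Yy1) had been deleted in the heart with a MerCreMer transgene, a Cre recombinase held inactive by mutated oestrogen receptor domains until a ligand is given. The other 4 mice carried the MerCreMer transgene and served as controls. No unoperated heart was analysed here, so each comparison is between genotypes under pressure load, and the question it addresses is which transcripts, metabolic ones among them, depended on YY1 in the loaded heart. The libraries held 23869112 to 23966753 reads each, of which 14582605 to 16000455 were assigned to genes. The labels number separate mice, so the spread between libraries includes that between animals.

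The deleted gene itself was lower in the hearts labelled as knockouts. Yy1 (mm10 chromosome 12, 108792973 to 108820148, plus strand) stood at 21.04 ± 2.55 CPM (read counts scaled to library size; SD, n = 4) in the YY1 KO hearts and at 36.1 ± 1.58 CPM in the controls. The knockout level was 58.3% of the control level, and the values of the groups did not overlap. The log2 fold change was −0.78 ± 0.10 (SE), with an adjusted p of 0.000769 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A two-sided exact permutation test over the 70 assignments of the libraries gave p = 0.0286, the smallest value that this design allows. Whole heart also contains cells outside the cardiomyocyte lineage, and reads from undeleted exons still count toward the gene, so this level does not measure the extent of recombination.

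**Figure D1:**
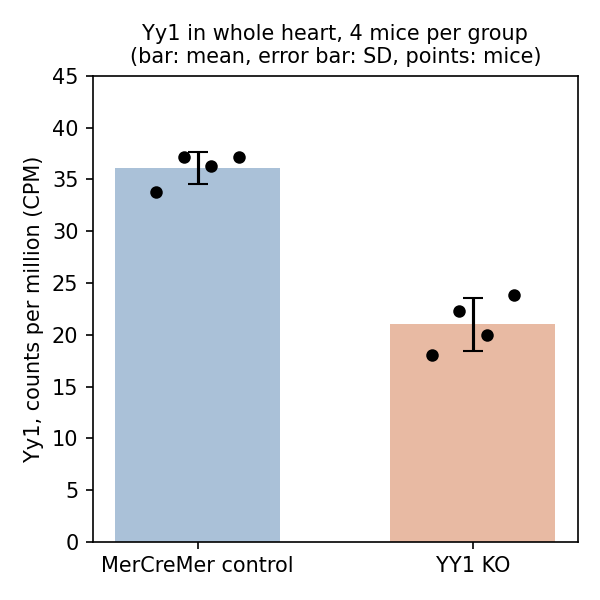
Yy1 expression in CPM in each mouse (points), with the group mean (bar) and SD (error bar) for 4 MerCreMer control and 4 YY1 KO hearts. Control hearts lay between 33.8 and 37.2 CPM, and YY1 KO hearts between 18.0 and 23.8 CPM.

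Of 13506 genes tested, 2911 (21.6%) were higher and 2337 (17.3%) lower in YY1 KO hearts at an adjusted p under 0.05 in edgeR's quasi-likelihood test. At least 2-fold differences were seen for 825 of the higher and 652 of the lower genes. Groups did not overlap for 38.3% of the tested genes, where chance would give 2.86%. The knockout effect was also the main axis of variation between libraries. The first principal component of the 2000 most variable genes held 60.8% of the variance and separated the genotypes, while the second held 22.8% and spread the mice within each genotype. Spearman correlations ranged from 0.960 to 0.991 between controls, from 0.973 to 0.990 between knockouts and from 0.924 to 0.972 across genotypes.

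**Figure D2:**
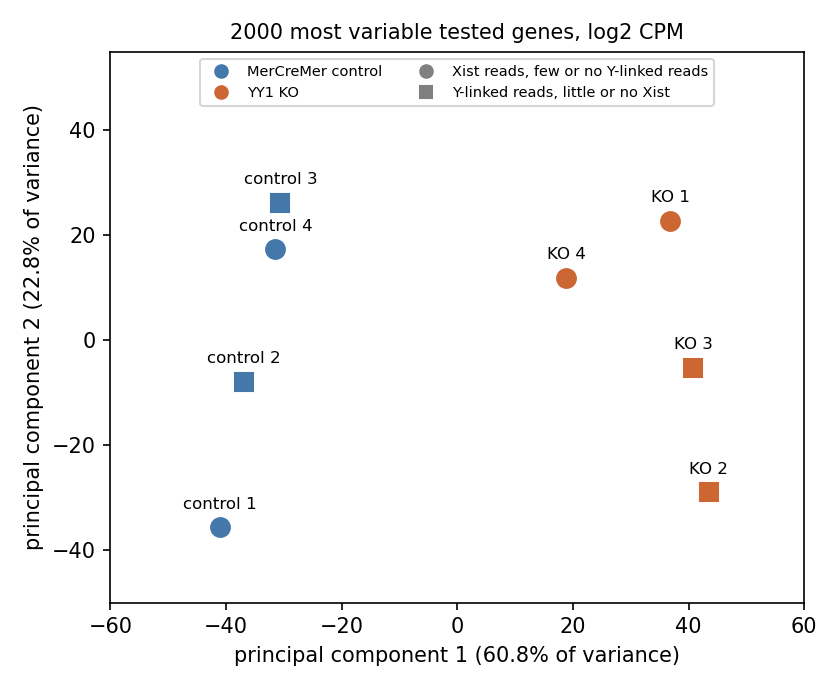
Principal components 1 and 2 of log2 CPM for the 2000 most variable tested genes, with colour for genotype and symbol for the sex-linked transcripts detected in each mouse. Component 1 (60.8% of variance) separates the genotypes, and control 1 lies at the edge of component 2 (22.8%).

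The transcripts that rose most were barely detected in control hearts. Ptprn2, a receptor-type tyrosine phosphatase family member of dense-core vesicles, reached 15.6 ± 4.82 against 0.272 ± 0.151 CPM (knockout against control, mean ± SD, n = 4; log2 fold change 5.82 ± 0.38, edgeR adjusted p = 0.000109). It lies on chromosome 12 (116485720 to 117276849), 7.69 Mb from Yy1. Eppk1, which encodes the cytoskeletal linker epiplakin, rose by a log2 fold change of 5.28 ± 0.60, the catalytically inactive phosphatase relative Styxl1 by 5.08 ± 0.47, and the dual-specificity phosphatase Dusp26 by 5.04 ± 0.62. Caly (4.54), Stpg1 (4.45), the angiopoietin-like factor Angptl7 (4.12), Ftcd (4.00), the actin-bundling gene Fscn2 (3.97), Tmem202 (3.95), the POU-domain factor Pou3f1 (3.75) and the ciliary gene Cfap46 (3.71) completed the 12 largest increases that met the naming rule, with edgeR adjusted p of at most 0.00877. For Ftcd, 64.3% of strand-resolved reads came from the opposite strand, so its value cannot be assigned to the annotated transcript. Without control 3 the log2 fold change of Eppk1 was 6.47, and without YY1 KO 2 that of Fscn2 3.06. The Fscn2 call was lost with limma-voom (log2 fold change 3.15, limma-voom adjusted p = 0.0541).

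Of the 12 decreases named by the same rule, that of Ces1d, a carboxylesterase that hydrolyses lipid esters, was the largest. It fell from 87.8 ± 55.8 CPM in controls to 2.19 ± 2.55 CPM in knockouts (log2 fold change −5.31 ± 0.75, edgeR adjusted p = 0.00105), and without YY1 KO 4, at 5.985 CPM, the knockout mean was 0.931 CPM and the log2 fold change −6.56. The medium-chain acyl-CoA synthetase gene Acsm5 fell by 4.21 ± 0.85 on the log2 scale. The sodium channel subunit gene Scn4b (−3.95 ± 0.41), the chloride channel gene Clcn1 (−4.30 ± 0.60), the adenylyl cyclase gene Adcy1 (−3.80 ± 0.32) and the neuronal nitric oxide synthase gene Nos1 (−3.56 ± 0.61) also fell. The remaining members of this group were the integrin gene Itgb6 (−4.67), Lingo3 (−4.52), Lrrc15 (−4.47), Bex1 (−3.88), Cpn2 (−3.81) and the homeobox gene Cux2 (−3.64), all with edgeR adjusted p of at most 0.00442. Without YY1 KO 4 the log2 fold changes of Lingo3 (−5.52), Lrrc15 (−5.48), Bex1 (−5.59) and Cux2 (−5.26) were larger too, and without control 1 that of Clcn1 was −3.62. Lrrc15 and Cpn2 both lie on chromosome 16, and 97.9% and 90.3% of their strand-resolved reads came from the opposite strand, so these decreases cannot be assigned to the annotated transcripts.

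Transcripts for the oxidation of fatty acids, the main fuel of the adult heart, were lower in knockout hearts. Of 36 measured members of the fatty acid uptake and oxidation list, 20 fell, 0 rose and 16 did not pass, and 24 fell when p was adjusted over the list alone. Acsl1, which activates long-chain fatty acids, fell from 1099 ± 265 to 417 ± 95.5 CPM (log2 fold change −1.40 ± 0.22). Cpt2, needed for their entry into mitochondria, fell by 1.44 ± 0.19 on the log2 scale. The β-oxidation genes Decr1 (−1.44 ± 0.24) and Echs1 (−1.31 ± 0.21) fell as well, with edgeR adjusted p of at most 0.00194 for these 4 genes. The list passed camera with a preset correlation (adjusted p = 1.21e-06), with adjusted p = 0.733 with an estimated correlation and 0.0517 in fry.

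Other mitochondrial lists were also called lower by camera. Among 77 nuclear-encoded subunits of oxidative phosphorylation, 32 fell and 3 rose (34 and 3 adjusted over the list alone). Examples are the complex I genes Ndufc1 (−1.29 ± 0.15), Ndufb8 (−1.14 ± 0.15) and Ndufa5 (−1.40 ± 0.19) and the complex III gene Uqcrc1 (−1.09 ± 0.16). In the list for the TCA cycle and pyruvate entry, 10 of 24 members fell and 1 rose, the same counts as adjusted over the list alone. The pyruvate dehydrogenase genes Pdhb (−1.05 ± 0.14) and Pdhx (−0.95 ± 0.13) were each lower, as were Sucla2 (−1.06 ± 0.16) and Idh3b (−0.99 ± 0.16). Of 23 genes for the catabolism of branched-chain amino acids and ketones, 12 fell and 0 rose, 12 adjusted over the list alone, with Mccc1 at −1.43 ± 0.19 and Dbt, part of the branched-chain keto acid dehydrogenase, at −1.48 ± 0.23. These genes had edgeR adjusted p of at most 0.00190. The 3 lists passed camera in the order given, at adjusted p = 1.85e-05, 0.000639 and 0.000317. With an estimated correlation the adjusted p was 0.847, 0.775 and 0.733, and in fry 0.1295, 0.0569 and 0.0422. The groups overlapped in the mean of the oxidative phosphorylation list, as control 3 (−0.080 on the log2 scale, relative to the mean of the 8 libraries) lay below YY1 KO 2 (−0.031). The count of higher oxidative phosphorylation genes was 1 without control 2, 3 or 4 or YY1 KO 2 or 3, and that of higher TCA cycle genes 0 without control 2 or 4.

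Genes that maintain mitochondria moved in part with these. Of 77 mitochondrial ribosomal protein genes, 28 fell and 9 rose (32 and 11 adjusted over the list alone). Mrps9 (−1.13 ± 0.13), Mrps24 (−1.13 ± 0.13) and Mrpl50 (−1.05 ± 0.12) fell, whereas Mrpl33 rose (1.03 ± 0.090). Among 29 regulators of mitochondrial biogenesis, 11 fell and 0 rose, 11 adjusted over the list alone, including the coactivator gene Ppargc1b (−0.84 ± 0.12), the retinoid receptor gene Rxra (−0.74 ± 0.11), the mitochondrial DNA polymerase gene Polg (−0.54 ± 0.090) and the corepressor gene Ncor1 (−0.52 ± 0.088). Camera gave adjusted p = 0.000618 for the ribosomal list and 0.000317 for the regulators, and with an estimated correlation adjusted p = 0.775 and 0.577. In fry the adjusted p was 0.0545 and 0.0170. Without control 3 or YY1 KO 3, 5 ribosomal genes rose, and without control 1, 1 regulator rose. In the list for mitochondrial dynamics and mitophagy, 6 of 22 members rose and 2 fell (7 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.397). Its increases included the autophagy receptor genes Sqstm1 (0.95 ± 0.14) and Bnip3 (1.31 ± 0.31) and the ubiquitin ligase gene Park2 (1.01 ± 0.16). No mitochondrially encoded transcript is listed in the tables used, so that list was not analysed here.

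Glycolytic and antioxidant genes moved in both directions. Of 26 genes for glucose uptake and glycolysis, 9 rose and 7 fell (10 and 8 adjusted over the list alone), and camera did not call the list (adjusted p = 0.934). The hexokinase genes went opposite ways, with Hk2 at 237 ± 41.0 against 527 ± 45.5 CPM (knockout against control; log2 fold change −1.16 ± 0.14) and Hk1 at 601 ± 109 against 319.7 ± 13.1 CPM (0.91 ± 0.14). The muscle enolase gene Eno3 (−1.17 ± 0.19) and Pfkfb2 (−1.24 ± 0.16), which sets the level of a phosphofructokinase activator, fell. In the antioxidant list 10 of 30 members rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.493). The mitochondrial peroxidase gene Prdx3 (−1.11 ± 0.16) and Prdx6 (−0.89 ± 0.14) fell, whereas Gpx1 (0.88 ± 0.13) and the glutathione synthesis gene Gclc (0.84 ± 0.15) rose.

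Genes of the integrated stress response and of serine and folate metabolism rose together. Of 28 measured members, 18 rose and 0 fell, and 20 rose when adjusted over the list alone. The transcription factor gene Atf5 went from 49.8 ± 6.39 to 185 ± 23.5 CPM (log2 fold change 1.90 ± 0.13, edgeR adjusted p = 0.000109). Asns, the asparagine synthetase gene, rose by 3.53 ± 0.33, the pseudokinase gene Trib3 by 3.43 ± 0.27 and the mitochondrial folate enzyme gene Mthfd2 by 3.41 ± 0.38. The list passed camera (adjusted p = 1.97e-06), with adjusted p = 0.459 with an estimated correlation and 0.00173 in fry. The endoplasmic reticulum folding list moved the other way, as 8 of 22 members fell and 0 rose (8 fell adjusted over the list alone). The chaperone genes Hspa5 (−0.82 ± 0.14), Sdf2l1 (−0.93 ± 0.16), Manf (−0.59 ± 0.12) and Hsp90b1 (−0.38 ± 0.092) were lower (camera adjusted p = 0.0101, with adjusted p = 0.577 with an estimated correlation and 0.0160 in fry). Without YY1 KO 3, 5 members of this list fell, and without control 1 or 4, 1 rose. Among p53 targets, 10 of 25 rose and 1 fell (0 without control 2), the same counts as adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a (2.08 ± 0.26), Trp53inp1 (1.65 ± 0.21), Mdm2 (0.44 ± 0.080) and Rrm2b (0.66 ± 0.12) rose (camera adjusted p = 0.00436, with adjusted p = 0.577 with an estimated correlation and 0.00778 in fry).

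**Figure D3:**
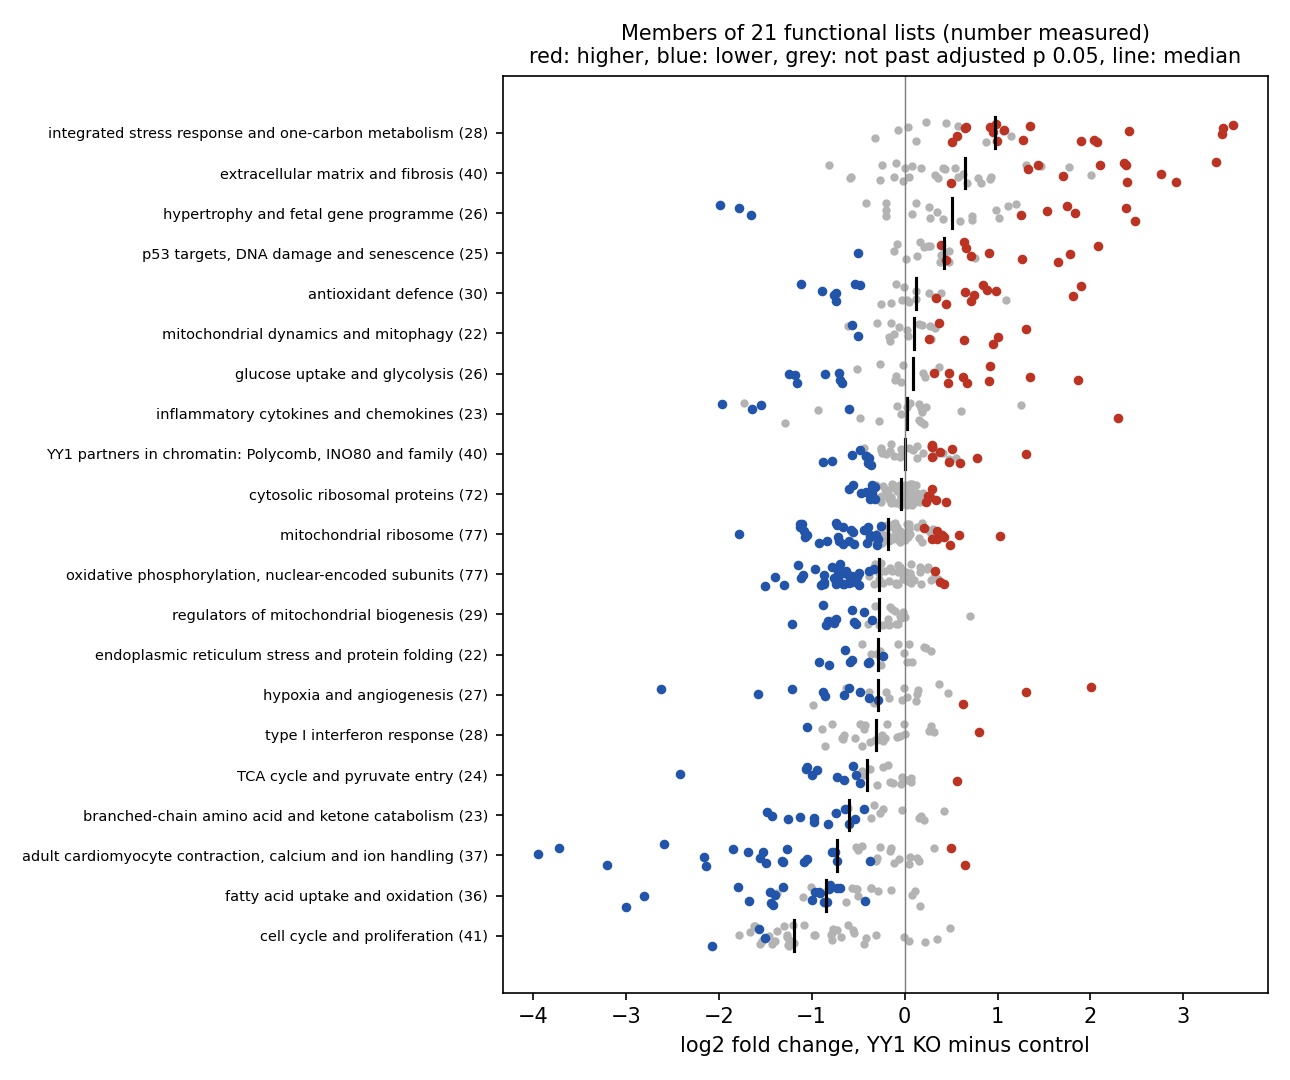
Log2 fold change (YY1 KO minus control) of each measured member of 21 functional lists, ordered by the list median (black line), with red for members higher and blue for members lower at an edgeR adjusted p under 0.05 and grey for the rest. In fatty acid uptake and oxidation 20 of 36 members are lower and 0 higher, while in the integrated stress response list 18 of 28 are higher.

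Adult cardiomyocyte genes of contraction and ion handling were lower. Of 37 members 20 fell and 2 rose, with the same counts adjusted over the list alone. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 1.49 ± 0.22 on the log2 scale, and the mitochondrial creatine kinase gene Ckmt2 (−1.32 ± 0.17) fell as well. The list passed camera (adjusted p = 7.36e-06), with adjusted p = 0.577 with an estimated correlation and 0.00778 in fry. The count of higher members was 1 without control 1 or 2 or YY1 KO 2, and 0 without control 4 or YY1 KO 3. The hypertrophy and fetal gene list was mixed, with 6 of 26 members higher, 3 lower and the same counts adjusted over the list alone (camera adjusted p = 0.102). The intermediate filament gene Des rose from 3116 ± 474 to 11109 ± 2050.2 CPM (1.83 ± 0.19) and the actin regulator gene Enah by 1.53 ± 0.33, whereas Hopx (−1.99 ± 0.44) and Tuba8 (−1.65 ± 0.26) fell. Its members Myh7 (3844 to 9929 CPM in knockouts, 514 to 2655 in controls) and Nppb (1145 to 2021 against 220 to 1134) did not overlap between genotypes. These genes were chosen after their values were seen, and no test of them is given here. Groups did not overlap for 38.3% of all tested genes, and the gap for Nppb was narrow. Nppa and Acta1 did overlap. Control 1 had the lowest mean of this list (−1.37 on the log2 scale, relative to the mean of the 8 libraries), followed by control 2 (−0.38). The natriuretic peptide transcript Nppa was at 159.1 CPM in control 1, against 1213 to 4283 CPM in controls 2 to 4. Without control 1, 8 members of the list were higher and 3 lower. The list passed camera without control 3 (adjusted p = 0.0103) or control 4 (adjusted p = 0.0398).

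The extracellular matrix list was called higher and the hypoxia and angiogenesis list lower by camera. In the extracellular matrix list 11 of 40 members rose and 0 fell (10 rose adjusted over the list alone). Comp, a cartilage matrix gene, reached 79.0 ± 40.6 against 7.67 ± 4.20 CPM (log2 fold change 3.36 ± 0.46), and Tgfb2 (2.76 ± 0.44), Tgfb3 (1.33 ± 0.27) and Timp2 (0.50 ± 0.10) rose. The list passed camera (adjusted p = 0.00436), with adjusted p = 0.847 with an estimated correlation and 0.224 in fry. The groups overlapped in its mean, as YY1 KO 2 (−0.31 on the log2 scale, relative to the mean of the 8 libraries) lay below controls 3 (0.28) and 4 (0.32). Control 1 had the lowest mean of this list, and without it 10 members were higher, whereas without control 2 there were 7. Of 27 hypoxia and angiogenesis genes, 10 fell and 3 rose, as also adjusted over the list alone. Apln (−2.62 ± 0.39), the vascular growth factor genes Vegfa (−0.88 ± 0.12) and Vegfb (−0.60 ± 0.12) and the receptor gene Kdr (−1.21 ± 0.18) fell. Camera called this list lower (adjusted p = 0.0315), with adjusted p = 0.459 with an estimated correlation and 0.00778 in fry. The camera call was lost without control 4 (adjusted p = 0.0501) or YY1 KO 1 (adjusted p = 0.052, with 5 members higher).

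The cell cycle list was called lower by camera although few of its members passed alone. Of 41 genes, 3 fell (Ccnd1, Cenpf and Mcm2) and 0 rose, with 1 lower adjusted over the list alone. The cyclin gene Ccnd1 fell by 1.504 ± 0.319 and the kinetochore gene Cenpf by 2.07 ± 0.51 on the log2 scale. The Mcm2 call (−1.57 ± 0.44, edgeR adjusted p = 0.0206) was lost without control 3 (adjusted p = 0.0505) or YY1 KO 3 (adjusted p = 0.0648). Camera gave adjusted p = 0.0122 for the list, with adjusted p = 0.847 with an estimated correlation, 0.448 in fry, and 0.235, 0.0511 and 0.107 without control 3, control 4 and YY1 KO 2. The groups overlapped in the list mean, as YY1 KO 1 (0.45 on the log2 scale, relative to the mean of the 8 libraries) lay above controls 1 (−1.18) and 2 (0.23). Control 1 was the lowest of the controls in this list, and without it 12 members were lower. Without control 3, 1 member was higher. Type I interferon genes (1 of 28 higher, 1 lower, camera adjusted p = 0.0566) and inflammatory cytokines and chemokines (1 of 23 higher, 4 lower, camera adjusted p = 0.243) did not pass as lists. The interferon list depended on the libraries, as camera called it lower without control 1, control 2, YY1 KO 1, YY1 KO 3 or YY1 KO 4 (adjusted p = 0.00745, 0.0345, 0.0347, 0.0121 and 0.03), and its count of lower members was 6 without control 1, 2 without YY1 KO 4 and 0 without control 2, 3 or 4 or YY1 KO 1 or 3. Of the cytokine list 8 members were lower without control 1, and 0 were higher without control 2 or YY1 KO 2 or 3 and 2 without YY1 KO 4. Adjusted over the list alone, 0 interferon genes were higher and 0 lower, and 1 cytokine gene was higher and 4 lower. The chemokine genes Cxcl1 (−1.54 ± 0.30), Cxcl9 (−1.65 ± 0.42) and Cxcl12 (−0.60 ± 0.13) fell, and Ifit2 rose (0.80 ± 0.20). For the cytokine list the median log2 fold change was above 0 (0.02) while its mean and the test pointed down.

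Chromatin partners of YY1 and cytosolic ribosomal protein genes showed no common direction. Of 40 Polycomb, INO80 and related genes, 9 rose and 9 fell (13 and 10 adjusted over the list alone), with a camera adjusted p of 0.967. Without control 2, control 4 or YY1 KO 1, 5 of them fell. Ino80 (0.78 ± 0.081) and Uchl5 (1.31 ± 0.15) rose, whereas Bmi1 (−0.78 ± 0.10) and Jarid2 (−0.88 ± 0.13) fell. Of 72 ribosomal protein genes, 6 rose and 10 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.157), with Rps13 at −0.56 ± 0.10 and Rpl21 at −0.47 ± 0.10. These counts moved with single libraries. The higher count was 1 without control 2, 3 without control 1 and 2 without control 3 or 4 or YY1 KO 1, 3 or 4, and the lower count was 6 without control 1 or 4 or YY1 KO 1, 5 without YY1 KO 2 or 3 and 16 without YY1 KO 4. Camera called the ribosomal list lower without control 2 (adjusted p = 0.0327) or YY1 KO 4 (adjusted p = 0.0187).

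Markers of vessels were lower and those of fibroblasts were not. Among 12 endothelial markers, 8 fell and 0 rose (8 and 1 adjusted over the list alone), including Emcn (−0.57 ± 0.10), Ushbp1 (−0.72 ± 0.12) and Tie1 (−0.66 ± 0.17). Among 12 smooth muscle and pericyte markers, 8 fell and 1 rose (10 and 1 adjusted over the list alone), including Rgs5 (−0.85 ± 0.14), Vtn (−1.24 ± 0.19), Abcc9 (−1.34 ± 0.27) and Kcnj8 (−0.72 ± 0.14). Ventricular cardiomyocyte markers fell in 7 of 14 cases and rose in 0, 7 lower adjusted over the list alone, with the myosin light chain gene Myl2 at −1.27 ± 0.21, Myl3 at −1.08 ± 0.20 and the myoglobin gene Mb at −1.84 ± 0.35. In the order given, the lists passed camera at adjusted p = 0.00572, 0.00359 and 0.0106. With an estimated correlation adjusted p = 0.830 for each of the 3 marker lists, and in fry 0.0644, 0.0211 and 0.0259. Of 12 fibroblast markers, 3 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.4997). Each of these calls was lost without some libraries, Cygb without control 2 or YY1 KO 3, Serpinf1 without control 2 or YY1 KO 1 or 3, Pdgfra without control 1 or 2 or YY1 KO 3 or 4, and Clec3b, the lower one, without YY1 KO 1 or 3 (adjusted p from 0.0516 to 0.0848). The higher count was 0 without control 2 or YY1 KO 3, and the lower count 0 without YY1 KO 1 or 3 and 2 without YY1 KO 4.

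The other marker lists did not pass camera, and most of their counts moved with single libraries. Of 6 Schwann cell and neuronal markers 3 fell, among them Dbh, the noradrenaline synthesis gene (−2.75 ± 0.45, and −3.40 without YY1 KO 4; camera adjusted p = 0.0729). Only 1 fell without control 2 or YY1 KO 2 or 3, while camera called the list lower without control 3, control 4 or YY1 KO 1 (adjusted p = 0.0152, 0.0413 and 0.0473). Immediate early genes were split, with 2 of 16 higher, 5 lower, Ier3 at 1.20 ± 0.22 and Nr4a1 at −1.48 ± 0.28 (camera adjusted p = 0.313). Of these, 9 were lower without control 1, where camera called the list lower (adjusted p = 0.0228), 2 without control 2 or YY1 KO 3, and 3 without control 3 or YY1 KO 2 or 4. Atrial markers (3 of 8 higher, 2 lower) included Pam (0.64 ± 0.14), and circadian genes (2 of 15 higher, 0 lower) included Clock (0.60 ± 0.11), with camera adjusted p of 0.827 and 0.621. The count of lower atrial markers was 1 without control 1, control 2 or any 1 of the YY1 KO libraries. Of the circadian genes 1 was higher without control 4 or YY1 KO 3, and 1 was lower without control 1 or 3. Of 5 measured skeletal muscle markers, the troponin gene Tnnt3 rose (3.02 ± 0.51) and the muscle creatine kinase gene Ckm, also abundant in heart, fell (−3.20 ± 0.68, and −4.46 without YY1 KO 4). The mean of that list was below 0 while camera pointed up (adjusted p = 0.942). Blood and immune markers were few. Of 15 macrophage markers 1 fell (Timd4; 0 adjusted over the list alone), but 0 fell where any library other than YY1 KO 1 was left out, and 1 rose without control 3. Of 3 neutrophil markers 1 rose (S100a9), a call lost without control 2, control 4 or YY1 KO 3, and the count was 0 without YY1 KO 3 and 2 without control 1 or 3 or YY1 KO 1 or 4. Of 2 lymphocyte markers 1 fell (Cd4), and 0 without control 2, 3 or 4 or YY1 KO 1, 2 or 3. Of 3 adipocyte markers 1 rose. None of 4 erythroid and 2 epicardial markers passed, while 1 erythroid marker rose without YY1 KO 1 or 4.

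The sexes of the hearts differed from the description of the animals as male. Xist, the RNA of the inactive X chromosome, was at 138 to 219 CPM in controls 1 and 4 and YY1 KO 1 and 4, in which the summed Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty reached at most 0.134 CPM. The other 4 hearts had 162 to 196 CPM of these Y-linked transcripts and at most 0.385 CPM of Xist. Each pattern was present in 2 mice of each genotype. With a term for sex, 4980 genes were changed in edgeR's quasi-likelihood test, and 93.0% of the calls stayed past the threshold. Within the 4 Xist-positive hearts alone edgeR called 0 genes, with 3451 at an unadjusted p under 0.05, and within the 4 Y-positive hearts it called 3336. Control 1, low in load-responsive transcripts, is 1 of the 2 Xist-positive controls. These counts therefore do not show that the knockout effect differs between the sexes. Of the 16 lists called by camera, 15 were kept in the Xist-positive hearts, where the cell cycle list was lost (adjusted p = 0.407), and 9 in the Y-positive hearts, where oxidative phosphorylation (0.0793), the TCA cycle (0.0596), matrix (0.175), endoplasmic reticulum folding (0.0841), p53 targets (0.0841), hypoxia and angiogenesis (0.166) and ventricular cardiomyocyte markers (0.139) were lost.

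**Figure D4:**
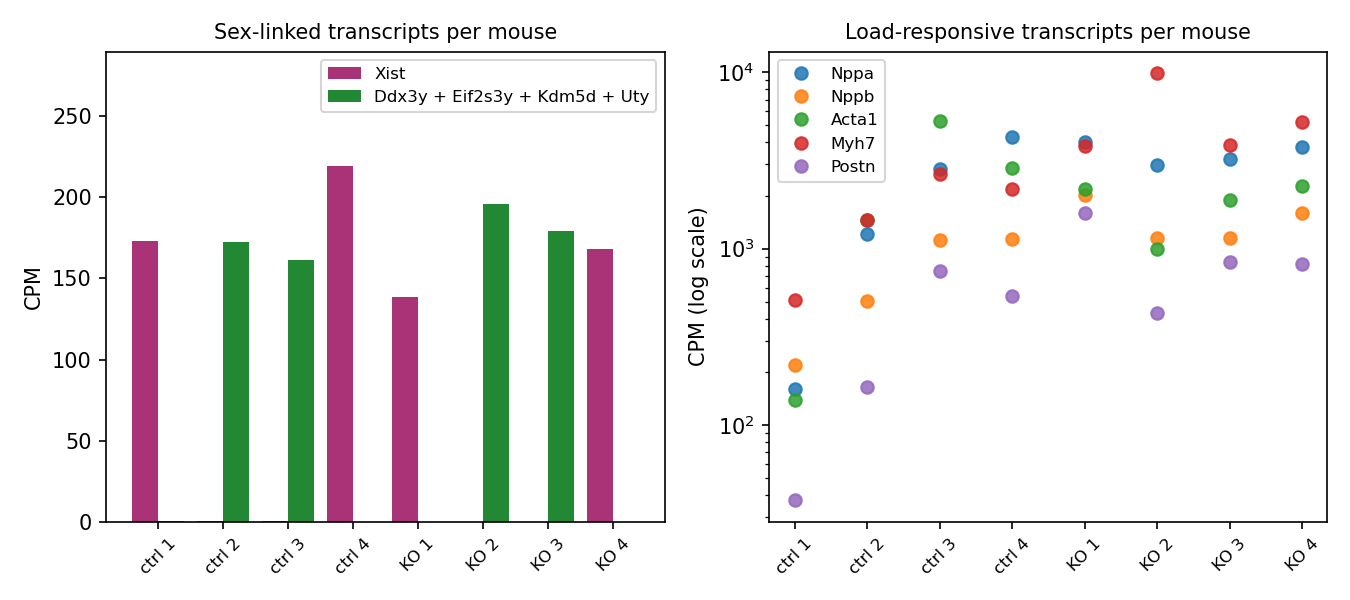
Left, CPM of Xist and of the sum of 4 Y-linked genes in each mouse. Right, CPM (log scale) of Nppa, Nppb, Acta1, Myh7 and Postn in each mouse, in which control 1 has the lowest value of the 8 mice for each gene (Nppa at 159.1 CPM).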

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

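Several tests in this part were chosen after the result was seen. They were those of mixed RNA from both sexes, the sex term, cardiomyocyte share and why control 1 was low in load-responsive transcripts. The others were recorded as set before their own results. Those of length and GC content and of the metabolic calls without control 1 name lists called lower or this library, however. Their choice therefore followed from the data. A library was picked out where its gap to the nearest value, as a share of the range of its group of 4, exceeded Dixon's 95% critical value, which was the case in 15 of 322 groups of named-gene values, and chance picks about 1 in 20. In control 1, Angptl7 (0.916 CPM), Cfap46 (0 CPM), Pam (858 CPM) and Wt1 (5.21 CPM) were lower than in the other controls. In control 2 Ptprn2 (0.498 CPM) and in control 3 Eppk1 (0.442 CPM) were higher than in the other controls, and in control 3 Plin4 (177.6 CPM) was lower. In YY1 KO 1, Scn4b (2.32 CPM), Clec3b (8.25 CPM) and Kcnj3 (12.3 CPM) were lower than in the other knockouts, as was Bst2 in YY1 KO 2 (10.5 CPM). In YY1 KO 4, Cux2 (4.36 CPM) and Myl4 (24.1 CPM) were higher and Cdkn1a (419.5 CPM) and Gpx1 (131.6 CPM) lower than in the other knockouts. Reads opposite to the annotated strand, which no comparison used on their own, differed between genotypes for 602 of 6677 genes tested in edgeR, 336 higher and 266 lower in knockouts. For 177 of the 555 that were also tested on the annotated strand, the annotated strand did not pass or went the other way.

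The 5248 changed genes were set against regrouped libraries. Of the 35 splits of the 8 libraries, 1, the real one, gave as many changed genes, and the highest other split gave 5. Every other split mixed the genotypes within its groups, which widens the spread there and leaves few calls from the start. With 35 splits, 1 is also the lowest number possible. The splits show that the count goes with the genotype grouping, but cannot by themselves exclude chance. The number of gene lists did not set the real split apart. As many lists as the 16 of the real split were past the camera threshold in 14 of the 35 splits, and the highest other split gave 22. A camera call at the preset correlation therefore does not set the genotypes apart from other groupings of these mice. The counts of changed members rest on the gene tests.

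The first pattern is Xist in 4 hearts described as male. Mixed RNA from both sexes is argued against, since the Y-linked sum in these libraries was at most 0.0760% of the median of the other libraries. Female origin has the values it needs, as the escape genes Kdm5c, Kdm6a, Eif2s3x and Ddx3x (transcribed from the inactive X chromosome) were higher in the Xist-positive hearts of each genotype, by a median of 0.79 on the log2 scale. Each pattern was equally frequent in both genotypes, so a difference between the sexes could not stand in for that between genotypes. For the same reason a term for sex could not take up the genotype difference. That 93.0% of calls stayed past the threshold with it is therefore no separate evidence. Whether the genotype effect differs between the sexes was not tested. Whether the animals or the description were mistaken cannot be read from the counts, and no biological explanation was tested for this pattern.

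The second pattern is the lower metabolic transcripts in knockout hearts. A smaller share of cardiomyocytes would raise markers of the other cell types alike. Instead the endothelial median lay 0.94 below the fibroblast median on the log2 scale (a difference of −0.94). A permutation test that exchanged genes between these lists gave adjusted p = 0.00596. It treats genes as independent and does not measure the spread between mice. For the endothelial list, camera with an estimated correlation gave adjusted p = 0.830 and fry 0.0644. A smaller share as the whole cause would not give this order of medians. Whether the order holds across mice was not tested, so a smaller share is not excluded, and more fibroblasts stay possible. After transcript length and GC content were regressed out, 5 of the 5 metabolic lists were still called lower by camera at the preset correlation. Such calls did not set the genotypes apart from other groupings, so they cannot decide on a length or GC trend. Across tested genes the log2 fold change was only weakly related to length (Spearman −0.10) and GC content (−0.013). Control 1 alone does not account for the lower metabolic transcripts, as 84.3% of the 102 lower calls among members of these lists remained without it. Control 2 leaned the same way, however. Its fatty acid list mean (0.61) was above those of controls 3 (0.02) and 4 (0.24), and its hypertrophy list mean (−0.38) below theirs (0.37 and 0.10). In the fatty acid list control 3 still lay above every knockout (highest −0.11). Among the knockouts, YY1 KO 1 had the highest hypertrophy mean (0.55) and the lowest fatty acid mean (−0.98). YY1 KO 2 had the lowest hypertrophy mean (0.090) and the highest fatty acid mean (−0.11). YY1 KO 3 (0.20 and −0.42) and YY1 KO 4 (0.44 and −0.27) did not follow this order. Control 3, however, lay above YY1 KO 2 and 3 in both means. Whether the lower metabolic transcripts follow the response of each heart to load was not tested, so a part of that response is not excluded. Loss of YY1 may lower these transcripts, as a hypothesis, and the list-level calls carry the limit given above for regrouped libraries.

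The third pattern is control 1, low in load-responsive transcripts. Depth and stray reads are argued against, since its gene reads and its opposite-strand share (3.54%) lay within the range of the other 7 libraries. Among the controls sex stays open, because in the mean of the hypertrophy list control 4, also Xist-positive, lay 0.48 farther from control 1 on the log2 scale than the Y-positive control 2 and 0.27 nearer than the Y-positive control 3, and 4 controls are too few to decide. The bound for sex, first set against 1 Y-positive control, which would have argued against it, was set against both after these distances had been seen. Among the knockouts, the Xist-positive hearts had higher means of this list (0.55 and 0.44) than the Y-positive ones (0.090 and 0.20). These values argue against low levels in Xist-positive hearts in general, for the knockouts they cover. A weaker pressure load in this mouse may be the reason, with Nppa at 13.1% of the lowest other library, but pressure gradients and heart weights were not analysed here, which keeps this open.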

How the results depend on the processing

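The within-sex fits were chosen after the result was seen, as was the sex term, and the other alternatives were set before. The count of 5248 changed genes stayed within 1.5 times under the scaling, test, filter, strand, block, surrogate-variable and sex-term alternatives (4026 to 6925), and from 3860 (without YY1 KO 3) to 5233 (without YY1 KO 4) with a library left out. Among the genes tested in both, 0 of the calls changed sign except under stranded counts, where 7 did. The balance of directions moved with the scaling, from 2653 higher and 2523 lower with RLE to 3339 higher and 1909 lower with library size alone. Leaving out mitochondrially encoded genes was not run, as none are listed. The Xist-positive hearts alone gave 0 changed genes in edgeR (0 higher, 0 lower, 0 at least 2-fold, 3451 at an unadjusted p under 0.05) and a Yy1 log2 fold change of −0.76 (adjusted p = 0.116, against 3.48e-10 to 0.00609 over the alternatives on all hearts or with 1 left out). The Y-positive hearts alone gave 3336 changed genes, 1730 of them higher. Only 2 hearts per genotype enter each, and the cause of the difference between them was not tested. For gene lists, 16 passed, against 0 with an estimated correlation and 9 with fry, which tests another question, and 14 in the Y-positive and 16 in the Xist-positive hearts, with 9 and 15 of the 16 kept. Counts of changed list members that moved by over 1.5 times and by at least 4 genes, on all hearts or within a sex, were these. With a surrogate variable, lower calls went from 20 to 31 in fatty acid oxidation, 3 to 25 in the cell cycle, 1 to 8 in the interferon and 4 to 8 in the cytokine list, and higher calls from 3 to 8 in oxidative phosphorylation, 6 to 15 in hypertrophy, 11 to 27 in matrix and 9 to 15 in the YY1 partner list. With the replicate block, 11 higher matrix calls became 6, 9 lower YY1 partner calls 5, and 6 higher and 10 lower ribosomal protein calls 2 and 5. With library size alone, 6 higher calls in mitochondrial dynamics became 10, 9 lower YY1 partner calls 5 and 10 lower ribosomal protein calls 4. With DESeq2, lower calls went from 10 to 17 in ribosomal proteins, 1 to 6 in the interferon and 4 to 8 in the cytokine list. Higher ribosomal protein calls went from 6 to 2 with RLE scaling or without a filter. In the Xist-positive hearts every list had 0 changed members in edgeR. In the Y-positive hearts, lower calls went from 32 to 16 in oxidative phosphorylation, 20 to 9 in fatty acid oxidation, 10 to 6 in the TCA cycle, 11 to 6 in the biogenesis regulators, 28 to 18 in the mitochondrial ribosome, 3 to 24 in the cell cycle, 10 to 5 in hypoxia, 7 to 3 in the antioxidant, 9 to 4 in the YY1 partner and 10 to 2 in the ribosomal protein list and 5 to 11 among immediate early genes. Higher calls there went from 9 to 5 in glycolysis, 10 to 4 among p53 targets, 9 to 5 in the YY1 partner and 6 to 0 in the ribosomal protein list and 0 to 4 among erythroid markers. The first component held 60.8% of variance, 57.0% with all tested genes and 57.0 to 67.8% with a library left out. Same-numbered mice did not deviate together (correlations −0.46, 0.34, −0.06 and 0.27, none best with its own number). They did share the sex-linked pattern at every number, and so few correlations cannot exclude pairing. Whether the numbers pair the mice therefore stays open. With the replicate number as a block 4026 genes were changed, and Yy1 fell by 0.79 on the log2 scale.

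Direction turned for results that were past no threshold either way, and the cause was not tested. A list's direction here is the sign of the mean log2 fold change of its members, a definition chosen after the camera directions had been seen. By camera's own direction 28 of 828 pairs of list and setting turned, 1 of them for a list past the threshold (in the Xist-positive hearts). In those hearts the log2 values were 0.026 for Cd68, 0.024 for Csf1r, 0.57 for Cd79a, −0.36 for Plin4, −0.40 for Alas2 and −0.21 for Bpgm. List means there were −0.055 (glycolysis), −0.031 (mitochondrial dynamics), 0.011 (interferon), 0.0062 (cytokines), −0.012 (YY1 partners), 0.095 (macrophage), −0.57 (neutrophil), 0.026 (lymphocyte), −0.10 (adipocyte), −0.18 (erythroid), 0.19 (skeletal muscle), 0.044 (immediate early) and −0.024 (circadian). In the Y-positive hearts they were 1.01 for Mmp9, −0.054 for Krt18 and −0.10 for the epicardial list. Cd79a was at 0.21 with limma-voom, 0.081 with the replicate block and 0.14 with a surrogate variable, the skeletal muscle list at 0.10 with a surrogate variable and the ribosomal protein list at 0.0052 with library size alone. With a library left out, Mmp9 ranged from −0.56 to 0.49, Cd79a from −0.45 to 0.60 and the skeletal muscle list from −0.28 to 0.050. At this depth, genes with few reads such as Cd79a, near 0.6 CPM, limit what can be called.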

Other observations

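The test of non-coding genes and the motif test at matched expression were chosen after the result was seen, and the motif and chromosome 12 tests were set before. Genes near Yy1 on chromosome 12 included Ptprn2, the largest of the increases that met the naming rule. Beside Ptprn2, the acute-phase gene Serpina3n, 4.39 Mb away, rose from 21.8 to 207 CPM (log2 fold change 3.24, edgeR adjusted p = 0.00159). Bcl11b, a zinc finger gene 0.88 Mb away, fell by 2.77 on the log2 scale. The matrix gene Fbln5 rose by 1.14 and Adssl1, for muscle adenylosuccinate synthesis, by 1.16. These genes were named after their values were seen. A candidate explanation is strain variants that travelled with the floxed allele. Within 10 Mb, 53 of 119 genes (44.5%) were called against 38.7% elsewhere (odds ratio 1.27, 95% confidence interval 0.867 to 1.86, Fisher's exact p = 0.219), so linked variants and an effect of YY1 cannot be told apart for this region.

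Genes with a YY1 motif (AANATGGCG, where N is any base) in the first 100 bases of an annotated transcript were called lower more often than others. Of 645 such protein-coding genes, 260 (40.3%) were lower, against 16.5% of the genes without it (odds ratio 3.41, 95% confidence interval 2.88 to 4.03, Fisher's exact p = 1.11e-43). Within 5 classes of mean expression the odds ratio was 3.09. They were higher less often (odds ratio 0.51, 11.9% against 21.05%). The reversed motif, as a control, gave 1.11 for lower calls but occurs in only 26 genes (95% confidence interval 0.326 to 3.02), so it bounds the background of such sequences loosely. Genes with the motif that fell, named after their values were seen, included Clybl (−1.53), Alkbh7 (−1.52), Isca2 (−0.89), Bcl11a (−2.44), Mrps24 (−1.13) and Ndufc1 (−1.29). Of 14 oxidative phosphorylation genes with the motif 11 fell, of 13 mitochondrial ribosome genes 6, and of the fatty acid oxidation genes 2 of 2 among 36 searched. The motif lay in 14 of 77 oxidative phosphorylation and 13 of 77 mitochondrial ribosome genes, against 645 of 12927 protein-coding genes. Gene class was not matched, so the odds ratio may in part reflect these lists, which camera called lower. In the whole lists 32 of 77 and 28 of 77 genes fell. Members with the motif fell more often in each, but this was not tested. A direct loss of activation at part of the lower genes stays a hypothesis, as binding was not measured. Most of the fatty acid oxidation genes that fell had no such motif in the stretch searched.

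Non-coding genes were over-represented among the higher calls. Of 494 tested, 212 (42.9%) were higher and 39 (7.89%) lower, against 20.6% and 17.7% of 12927 protein-coding genes. At matched mean expression the odds ratio for a higher call was 3.63 (95% confidence interval 2.99 to 4.40). An example is the antisense gene 1500015A07Rik, which rose from 1.94 ± 0.379 to 21.9 ± 2.32 CPM (3.49 ± 0.16, edgeR adjusted p = 2.07e-05), chosen after its value was seen. Antisense and overlapping genes share reads in counts taken irrespective of strand, which was not separated in this test.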
